A study of Lactococcus lactis with 4 samples.

How the data were processed

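Lactococcus lactis NZ9000, the parent, and WH101, an acid-tolerant strain made by genome mutagenesis, were grown in GM17 medium with 0.5% glucose at 30 °C without shaking, per the labels' protocols. Exponential-phase cells were held at pH 4 for 4 h for the stressed groups. RNA was sequenced by BGI after removal of rRNA, per the labels' protocols. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

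The authors deposited 4 full tables, each for a pair of libraries, and their filtered versions. The count of reads per gene was made by the authors and is unscaled: whole numbers whose sums give the reads in genes of each library. The deposited RPKM is the authors' count divided by gene length and by the library's reads in genes, which was recomputed and checked. The deposited log2 ratio was made by the authors from the RPKM values, with an RPKM of 0 replaced by 0.001. The deposited p-value belongs to the pair of libraries of its table, with no test named in the file headers, and is not used here. The authors' FDR column is treated as a score, because the tables hold 12 to 17 cells above 1 in all but the NZ9000 comparison. The authors' filtered tables keep genes with an absolute log2 ratio of at least 1 and an FDR score of at most 0.001.

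The tables together list 2410 genes. A gene absent from a table (16 genes are listed in only some) was taken to have no reads in its libraries, which the other tables bear out where they hold the same library. Functions come from the deposited best protein hits, KEGG and GO columns. The reference table, of Lactococcus lactis subsp. lactis 14B4 (assembly ASM317683v1), belongs to another strain, so it gave symbols only: 39 genes matched by protein accession, and 303 had a symbol from it or from the product text. No coordinates are printed. The tables hold 0 rRNA or tRNA genes. Reads shared by near-identical copies, such as transposases or cold shock genes, cannot be told apart from these tables, so those genes are uncertain.

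Groups came from the sample labels, 1 library per group, and the design gives 4 comparisons and the difference of the 2 acid responses. Counts were scaled by TMM factors over the 4 libraries (edgeR 4.0.16, R 4.3.3), which were 1.03, 0.957, 1.01 and 1.01 for NZ9000 pH 7, NZ9000 pH 4, WH101 pH 7 and WH101 pH 4. Folds used a prior of 0.5 reads. The size rule asked for at least 2-fold, at least 50 reads over the 2 libraries and a 95% exact conditional (Clopper-Pearson) interval of the ratio that excluded 1. For the difference of responses it asked for an absolute log2 difference of at least 1, 50 reads in each strain's pair and a normal counting interval that excluded 0. With 1 library per group no p-value was computed. The interval of the correlation came from 1000 resamples of genes.

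There were 32 gene lists, fixed with their matching words, and for each the median log2 fold was placed among 10000 random lists of the same size matched on 10 bins of mean expression. Medians below percentile 2.5 or above 97.5 are said to stand apart. Lists of fewer than 3 measured genes have no percentile: glutamate decarboxylase and the nisin regulators, of which nisR alone was identified. The malolactic and citrate list had 0 members. The text names, per comparison, the 8 annotated genes that rose most and the 8 that fell most among those past the rule (6 and 6 for the difference), and nisR. Members of described lists are named from the 2 highest and 2 lowest, though not all of these, and a gene named for one comparison may be given in another. The lists, the rules, the comparisons and the alternatives were chosen before the data were examined, except where the text says that a choice came after.

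The scripts were tested on simulated Poisson counts built on each gene's mean over the 4 libraries, with 200 genes changed. For NZ9000 pH 4 against pH 7, over 2207 genes, the rule called 1 of 67 genes changed 1.5-fold, 67 of 67 changed 2.5-fold and 66 of 66 changed 4-fold, and 2 of 2007 unchanged genes. For the difference of responses, over 2201 genes, it called 66 of 67, 67 of 67 and 66 of 66 changed by those folds in opposite directions. Random lists of 12 unchanged genes stood apart in 2 of 200 cases and lists shifted by 0.5 in 50 of 50. These lists were drawn gene by gene, so the test does not cover lists of genes that move together. The simulated counts hold counting error only, so the numbers of genes called leave out variation between cultures or preparations.

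Alternatives were scaling by total gene reads, by DESeq2 1.42.0 size factors or by the upper quartile, a read minimum of 500 or none, limits of 4-fold and 1.5-fold, a prior of 5 reads, the authors' RPKM values with 1 added before the logarithm, the authors' own calls, leaving out the 10 genes with most reads, list membership by symbol alone, and random lists not matched on expression or drawn without ribosomal proteins. Counts on the 2 cross pairs of libraries and a correlation over genes past the rule in neither strain were added after seeing the data. The splits of the libraries 2 against 2 were not among the choices fixed before. Each comparison of groups uses exactly 2 libraries, and the difference of responses, the correlation and the splits of the libraries use all 4, so none could be rerun without a library that might be doubted. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.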

Results

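RNA of Lactococcus lactis was sequenced from 4 cultures, 1 library per group: the parent strain NZ9000 and the acid-tolerant strain WH101, each labelled pH 7 or pH 4. Exponential-phase cells in the pH 4 groups had been held at pH 4 for 4 h. The libraries held 16985857 reads in genes for NZ9000 pH 7, 16954792 for NZ9000 pH 4, 16995565 for WH101 pH 7 and 16981601 for WH101 pH 4, over 2410 genes. There were no replicates, so no difference below has a replicate check, and every interval in brackets is a 95% exact (Clopper-Pearson) interval, unless marked as a normal approximation, and covers counting error only. A gene is said to have risen or fallen when its scaled reads differed at least 2-fold between 2 libraries, with at least 50 reads over both and an interval that excluded a ratio of 1. Such a statement compares those libraries, not the conditions.

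The libraries paired across strain and pH. The library labelled NZ9000 pH 7 and the library labelled WH101 pH 4 had 6 genes past the size rule, and the library labelled NZ9000 pH 4 and the library labelled WH101 pH 7 had 13. The remaining pairs had 93, 134, 187 and 199. Every direction given below between strains or between pH values rests on the labels as deposited. Each of the 4 comparisons sets a library from the pair with 6 genes against a library from the pair with 13. The comparisons, and the difference of responses, therefore largely repeat the same contrast, in some with the sign reversed. They are not separate findings. The counts of 6 and 13 were 27 and 37 with no read minimum and 1 and 5 with a minimum of 500.

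**Figure D1:**
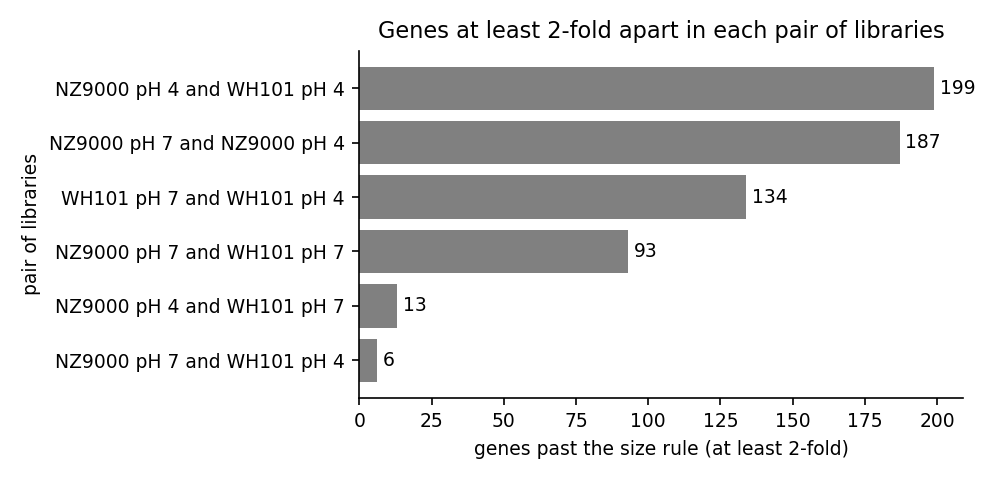
Bars give the number of genes past the size rule (at least 2-fold) for each of the 6 pairs of libraries, 1 library per group. The pairs that cross strain and pH have 6 and 13 genes, and the pairs that share a strain or a pH have 93 to 199.

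The acid response of the parent strain was read from the library labelled NZ9000 pH 4 against the library labelled NZ9000 pH 7. Genes for making the vitamin thiamine rose most: thiamine phosphate synthase (LLNZ_RS06160) was 11.2-fold higher (log2 3.49 [3.31 to 3.68]), hydroxymethylpyrimidine kinase (LLNZ_RS06155) 9.18-fold and hydroxyethylthiazole kinase (LLNZ_RS06150) 7.39-fold. The nitrogen regulatory protein P-II (LLNZ_RS04665), a sensor of nitrogen supply, rose 7.36-fold, and the ammonia permease (LLNZ_RS04660) 5.40-fold (log2 2.43). Most fatty acid synthesis genes fell, led by 3-oxoacyl-ACP synthase III (LLNZ_RS08945), which starts each chain, at a log2 fold of -2.01 [-2.08 to -1.94]. In all, 126 genes rose and 61 fell of 2219 with enough reads. Scaled by total gene reads, 99 rose and 79 fell, and the authors' own calls gave 94 and 77.

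Several lists of amino acid and peptide genes stood above the random lists in NZ9000. Some of their genes have neighbouring locus tags and may move together, so the percentiles do not count independent genes. Of 9 branched-chain amino acid biosynthesis genes 8 rose, with a list median of 1.63, above all of the 10000 random lists matched on expression (percentile 100). The extremes were 2-isopropylmalate synthase (LLNZ_RS06525, log2 2.37) and an acetolactate synthase (LLNZ_RS06635, 0.39, under the 2-fold limit). Of 5 arginine deiminase genes, whose pathway breaks down arginine to ammonia and ATP, 4 rose (median 1.43, percentile 99.99), among them carbamate kinases LLNZ_RS11560 (1.97) and LLNZ_RS11565 (1.82) and arginine deiminase itself (LLNZ_RS11580, 1.40). In the glutamine and glutamate list 3 of 5 rose (median 1.18), including both glutamate synthase genes (LLNZ_RS06000, 1.76, and LLNZ_RS05995, 1.58). Histidine biosynthesis had 4 of 9 genes up (median 0.95, percentile 99.985). Peptide transport had 9 of 24 up (median 0.91, percentile 100), with the oligopeptide-binding protein oppA (LLNZ_RS03630) at 2.09 and a peptide permease (LLNZ_RS03625) at 1.97.

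Some sugar uptake genes rose as well in the library labelled NZ9000 pH 4: 7 of 18 phosphotransferase genes (median 0.80), such as a beta-glucoside transporter (LLNZ_RS02315, 1.43) and a fructose transporter (LLNZ_RS07900, 1.42), and 6 of 14 sugar ABC transporter genes (median 0.86), such as permease LLNZ_RS03825 (1.64). Also among the largest rises was 4-alpha-glucanotransferase (LLNZ_RS09365, 2.34). Pyruvate and mixed-acid metabolism went both ways: 5 of 20 genes rose and 1 fell (median 0.38, percentile 99.97). Those that rose included acetolactate synthase genes LLNZ_RS06490 (1.41) and LLNZ_RS06485 (1.40), which the branched-chain list also holds, and the one that fell was alpha-acetolactate decarboxylase (LLNZ_RS07390, -1.82). None of 57 ribosomal protein genes passed the 2-fold limit, but their median of 0.41 lay at percentile 100. Of 19 osmolyte, potassium and metal transport genes 2 rose (median 0.16, percentile 97.92), both for zinc uptake (LLNZ_RS12015, 1.90, and LLNZ_RS12010, 1.45).

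On the lower side in NZ9000, 11 of 13 fatty acid genes fell (median -1.40, percentile 0), with malonyl CoA-acyl carrier protein transacylase (LLNZ_RS08935) at -1.70 and dehydratase LLNZ_RS08915 at -1.64. A MarR family regulator (LLNZ_RS08950) fell to -1.96. The list's matching words did not take it in, but its locus tag lies beside that of LLNZ_RS08945. The biotin transporter bioY2 (LLNZ_RS01725) fell to -1.75; biotin is the cofactor of the first step of fatty acid synthesis. Cold shock proteins, small RNA-binding proteins, had 2 of 6 genes down (median -0.78, percentile 0.02): LLNZ_RS06355 at -1.31 and LLNZ_RS09230 at -1.22, both uncertain since near-identical copies can share reads. Purine biosynthesis had 2 of 15 down (median -0.67), including phosphoribosylaminoimidazole-succinocarboxamide synthase (LLNZ_RS04965, -1.19), while pyrimidine biosynthesis had a median of -0.56 with no gene past the limit. A bacteriocin gene (LLNZ_RS06350, -1.89) and a transposase (LLNZ_RS06420, -1.74, from 66 and 18 reads, uncertain for the same reason) completed the largest falls. Chaperones and proteases had a median of -0.21 (percentile 1.16) and cell wall genes -0.20 (percentile 1.75), with no gene past the limit in either. Trigger factor (LLNZ_RS02650) was the lowest chaperone, at -0.88, and clpB (LLNZ_RS05030) the highest, at 0.26.

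Several groups often studied in acid stress did not stand apart from matched random lists in NZ9000. The F1F0-ATPase, the proton pump of this bacterium, had a median of 0.12 over 8 genes, from -0.01 for atpF (LLNZ_RS09735) to 0.38 for the epsilon chain (LLNZ_RS09710). DNA repair (median -0.05), oxidative and thiol stress (0.00), peptidases (0.08), arginine biosynthesis (-0.17), cysteine and methionine (0.10), tRNA synthetases (0.01), two-component systems (-0.15), competence (0.11), transposases (-0.01) and the enzymes that modify rRNA or tRNA (-0.21) lay within the random range. Glycolysis was within it too (-0.15), with 1 of 17 genes down, phosphoglycerate mutase LLNZ_RS01840 (-1.03). Glutamate decarboxylase (LLNZ_RS05975, 0.10) and its antiporter (LLNZ_RS05970, 0.20) passed no limit, nor did the nisin regulator nisR (LLNZ_RS01655, 0.31). Phage genes had a median of 0.24 (percentile 99.62) and none of 32 past the limit. The phage list lay within the random range with a minimum of 500 reads or with none, the cell wall and metal transport lists with a minimum of 500 or with random lists not matched on expression, and the chaperone list with the latter; glycolysis stood below the random lists with a minimum of 500.

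**Figure D2:**
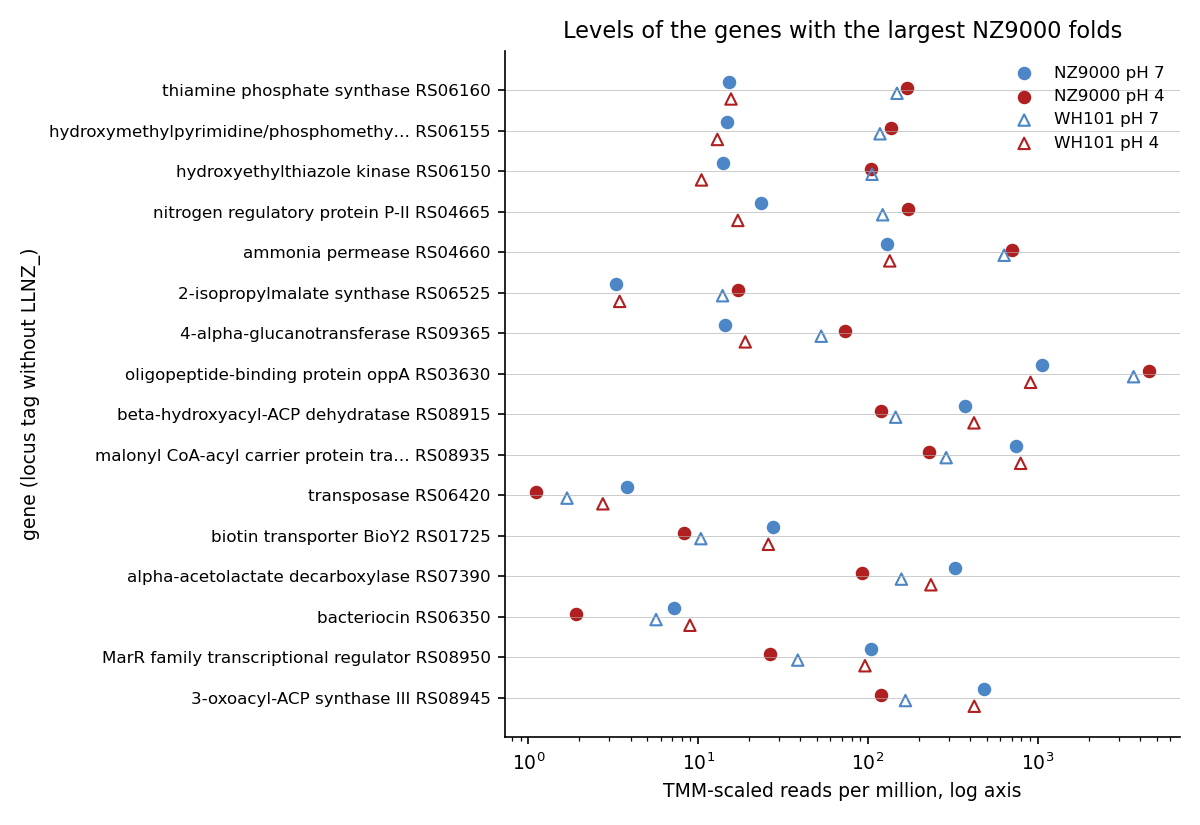
Points give TMM-scaled CPM (log axis) in each of the 4 libraries for the 8 genes that rose most and the 8 that fell most in NZ9000, 1 library per group. For thiamine phosphate synthase (LLNZ_RS06160) the libraries read 15.1 (NZ9000 pH 7), 170 (NZ9000 pH 4), 148 (WH101 pH 7) and 15.6 (WH101 pH 4).

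The acid response of the tolerant strain was read from the library labelled WH101 pH 4 against the library labelled WH101 pH 7. Here riboflavin (vitamin B2) and fatty acid genes were among those that rose. Lumazine synthase (LLNZ_RS07695) was 3.60-fold higher (log2 1.85 [1.81 to 1.89]), a bifunctional riboflavin gene (LLNZ_RS07700) 3.35-fold and riboflavin synthase (LLNZ_RS07705) 2.84-fold. The thiamine genes LLNZ_RS06150, LLNZ_RS06160 and LLNZ_RS06155 fell, to log2 folds of -3.33 [-3.56 to -3.11], -3.24 and -3.18, and P-II (LLNZ_RS04665) and the ammonia permease (LLNZ_RS04660) to -2.83 and -2.24. In all, 34 genes rose and 100 fell of 2224.

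Of 13 fatty acid genes 9 rose in WH101 (median 1.37, percentile 100), with fabF (LLNZ_RS08925) at 1.61, dehydratase LLNZ_RS08915 at 1.53 and the biotin carboxyl carrier protein LLNZ_RS08920 at 1.48. The ketoacyl-ACP reductase LLNZ_RS08930, which the list's matching words did not take in, rose to 1.67. The competence gene dprA (LLNZ_RS06460) rose to 1.66 from 13 to 42 reads; 2 others of 6 competence genes, comFC (LLNZ_RS07485, -1.19) and comEA (LLNZ_RS09760, -1.14), fell. Purine biosynthesis had a median of 0.55, but the only 1 of its 15 genes that rose, LLNZ_RS07710 (1.42), is by its product a riboflavin gene. Pyrimidine biosynthesis had a median of 0.56 with no gene past the limit. Smaller shifts without such genes stood above the random lists for glycolysis (0.32), chaperones and proteases (0.24, with groEL, LLNZ_RS02110, highest at 0.72) and tRNA synthetases (0.18).

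Below the random lists in WH101 were 9 lists, in some of which few or no genes passed the limit. Branched-chain synthesis had 8 of 9 genes down (median -1.41), the lowest being 2-isopropylmalate synthase (LLNZ_RS06525, -2.00); arginine deiminase 3 of 5 (median -1.07), with LLNZ_RS11560 at -1.76; glutamine and glutamate 3 of 5 (median -1.74); histidine 3 of 9 (median -0.86), with histidinol-phosphatase LLNZ_RS06535 at -1.21. Peptide transport had 11 of 25 down (median -0.97), from a peptide ABC transporter ATPase (LLNZ_RS10125, -2.18) and permease LLNZ_RS03625 (-2.07). Of 57 ribosomal protein genes 11 fell (median -0.71), with rpmC (LLNZ_RS11890) at -1.27 and rpsC (LLNZ_RS11900) at -1.21. Sugar ABC transporters had 2 of 14 down (median -0.59), phosphotransferase uptake none of 18 (median -0.51), and pyruvate metabolism 3 of 20 (median -0.26), the lowest an alcohol dehydrogenase (LLNZ_RS04835, -1.61). All of these medians lay at or below percentile 0.24 of the random lists. Genes with few reads among the largest falls were 2-dehydro-3-deoxygluconokinase (LLNZ_RS04430, -2.41 [-3.48 to -1.56]) and a molybdenum ABC transporter gene (LLNZ_RS06500, -2.14 [-3.35 to -1.19]).

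Among lists within the random range in WH101, 4 of 32 phage genes rose (median 0.07), among them holin (LLNZ_RS04360, 1.34) and the major tail protein (LLNZ_RS04320, 1.28). The zinc genes LLNZ_RS12010 (-1.06) and LLNZ_RS12015 (-1.05) fell in a metal transport list with a median of -0.09, and 1 of 15 oxidative stress genes fell, arsenate reductase LLNZ_RS04620 (-1.30). No gene passed the limit in the F1F0-ATPase (median 0.01), cold shock (-0.02), cell wall (0.13), DNA repair (0.09), peptidase (-0.02), arginine biosynthesis (0.27), cysteine and methionine (-0.33), two-component (0.03), transposase (-0.07) or rRNA and tRNA modification (0.04) lists. Glutamate decarboxylase and its antiporter had a median of -0.18, and nisR (LLNZ_RS01655) read -0.45. The arginine biosynthesis list stood above the random lists with no read minimum, with a minimum of 500 and with the authors' RPKM, and the competence list with no minimum.

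The strains were compared at pH 7 to ask how they differ without acid stress, if the labels hold. In the library labelled WH101 pH 7 the thiamine genes LLNZ_RS06160, LLNZ_RS06155 and LLNZ_RS06150 were 9.78-fold, 7.89-fold and 7.49-fold higher than in the library labelled NZ9000 pH 7 (log2 3.29 [3.11 to 3.48] for the first). P-II (LLNZ_RS04665) was higher by a log2 fold of 2.39, the ammonia permease (LLNZ_RS04660) by 2.28 and 2-isopropylmalate synthase (LLNZ_RS06525) by 2.08. The riboflavin genes LLNZ_RS07695, LLNZ_RS07700 and LLNZ_RS07705 were lower, at -1.72 [-1.76 to -1.68], -1.61 and -1.49, and 3-oxoacyl-ACP synthase III (LLNZ_RS08945) at -1.54. Of 2219 genes 67 were higher and 26 lower.

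Branched-chain synthesis was higher in WH101 at pH 7 (7 of 9 genes, median 1.37), as were the glutamine and glutamate list (3 of 5, 1.34), arginine deiminase (4 of 5, 1.05), peptide transport (10 of 24, 0.87) and histidine synthesis (2 of 9, 0.82). Phosphotransferase uptake (median 0.63), sugar ABC transporters (0.55), ribosomal proteins (0.35) and pyruvate metabolism (0.25) also lay above the random lists, with 1, 1, 0 and 2 genes higher, and 1 pyruvate gene, alpha-acetolactate decarboxylase (LLNZ_RS07390, -1.05), lower. Lower lists were fatty acid synthesis (9 of 13 genes, median -1.28), pyrimidine (-0.53) and purine synthesis (-0.45, with LLNZ_RS07710 alone past the limit, at -1.34), glycolysis (-0.26), chaperones (-0.23), the cell wall (-0.17) and tRNA synthetases (-0.12). Within the random range, the zinc genes LLNZ_RS12015 (1.48) and LLNZ_RS12010 (1.18) were higher, while the F1F0-ATPase (0.00) and cold shock proteins (-0.08) had no gene past the limit. Other large differences were in bioY2 (LLNZ_RS01725, -1.42), fabF (LLNZ_RS08925, -1.39), the MarR family regulator (LLNZ_RS08950, -1.42) and LLNZ_RS08930 (-1.48). So were a mobilization protein (LLNZ_RS06960, 1.91, from 18 and 68 reads) and the molybdenum transporter gene (LLNZ_RS06500, 1.92, from 12 and 46 reads). The histidine list lay within the random range with a minimum of 500 reads, and the tRNA synthetase list with random lists not matched on expression or drawn without ribosomal proteins. The cysteine and methionine list (median 0.35), within the range, stood above it with either of those random lists or with no read minimum.

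At pH 4 the question is how the tolerant strain differs under stress, if the labels hold. The library labelled WH101 pH 4 had less of the thiamine genes LLNZ_RS06160 (-3.44 [-3.63 to -3.26]), LLNZ_RS06155 (-3.40) and LLNZ_RS06150 (-3.31) than the library labelled NZ9000 pH 4, and less P-II (LLNZ_RS04665, -3.32), ammonia permease (LLNZ_RS04660, -2.39) and oppA (LLNZ_RS03630, -2.32). It had more of a bacteriocin gene (LLNZ_RS06350, 2.21 [1.66 to 2.83]) and of fatty acid genes, such as 3-oxoacyl-ACP synthase III (LLNZ_RS08945, 1.82) and LLNZ_RS08935 (1.79). Higher genes numbered 52 and lower genes 147 of 2219. Scaled by total gene reads the numbers were 69 and 123, and by the authors' calls 68 and 119.

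Fatty acid synthesis was higher in 10 of 13 genes at pH 4 (median 1.47), with LLNZ_RS08915 at 1.82 and LLNZ_RS08920 at 1.72. Outside that list, the MarR family regulator (LLNZ_RS08950) was higher at 1.85 and the ketoacyl-ACP reductase LLNZ_RS08930 at 1.75. Purine synthesis had 2 of 15 genes higher and 1 lower (median 0.76), the lower one, LLNZ_RS06550 (-1.18), being by its product a histidine gene, and pyrimidine synthesis 1 of 11 higher (0.57). Cold shock proteins had 1 of 6 higher (0.68), LLNZ_RS06355 at 1.11. The glutamate and gamma-aminobutyrate transporter yjeM (LLNZ_RS09965) was higher at 1.67. Medians of 0.21 for chaperones, 0.20 for glycolysis and 0.20 for the cell wall also lay above the random lists, with no gene past the limit. The glycolysis list lay within the random range with no read minimum, and it and the chaperone list did so with random lists not matched on expression; glycolysis and the cell wall did so with random lists drawn without ribosomal proteins.

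Lower at pH 4 were branched-chain synthesis (8 of 9 genes, median -1.58), the glutamine and glutamate list (3 of 5, -1.57), arginine deiminase (4 of 5, -1.46), peptide transport (12 of 25, -0.99), sugar ABC transporters (7 of 14, -0.99), histidine (3 of 9, -0.97), ribosomal proteins (20 of 57, -0.79), phosphotransferase uptake (7 of 18, -0.73), pyruvate metabolism (5 of 20 lower and 1 higher, -0.36) and metal transport (2 of 19, -0.19). The lowest of these genes was 3-isopropylmalate dehydrogenase (LLNZ_RS06520, -2.65, from 127 and 21 reads), and 2-dehydro-3-deoxygluconokinase (LLNZ_RS04430) stood at -2.35. The F1F0-ATPase (-0.14), phage genes (0.05) and DNA repair (0.11) lay within the random range with no gene past the limit.

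**Figure D3:**
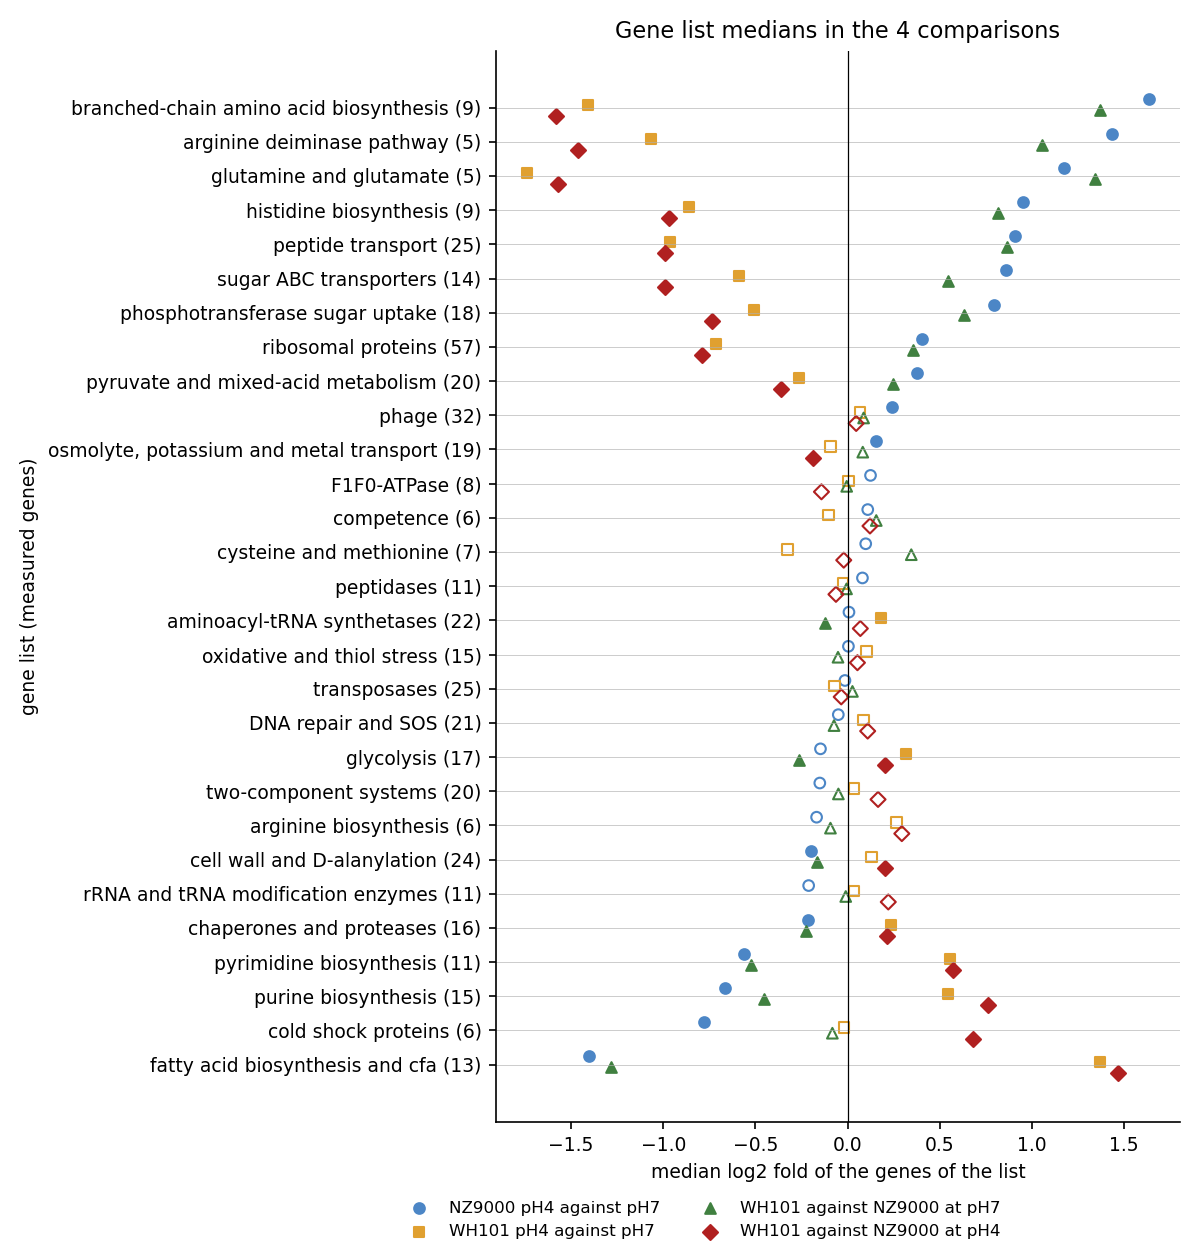
Points give the median log2 fold of each gene list in the 4 comparisons, filled where it lay outside the central 95% of 10000 random lists matched on expression and open where it did not, with the number of measured genes in brackets. Branched-chain synthesis reads 1.63, -1.41, 1.37 and -1.58 in the order of the key, and fatty acid synthesis -1.40, 1.37, -1.28 and 1.47.

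The difference of the acid responses asks whether the strains answered acid differently. By the labels as deposited, many genes went in opposite directions in the 2 responses. In WH101 minus NZ9000, thiamine phosphate synthase (LLNZ_RS06160) differed by a log2 fold of -6.73 [-6.99 to -6.47, normal approximation], P-II (LLNZ_RS04665) by -5.71 and the ammonia permease (LLNZ_RS04660) by -4.67. Fatty acid genes differed the other way, with LLNZ_RS08945 at 3.35. So did the ketoacyl-ACP reductase LLNZ_RS08930 at 3.22, the MarR family regulator (LLNZ_RS08950) at 3.28 and the biotin transporter bioY2 (LLNZ_RS01725) at 3.07. Of 2205 genes 153 differed upward by at least 2-fold and 295 downward.

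The lists with the lowest median differences were branched-chain synthesis (-3.08, 8 of 9 genes), glutamine and glutamate (-2.91, 3 of 5), arginine deiminase (-2.50, 4 of 5), peptide transport (-1.90, 17 of 24) and histidine synthesis (-1.82, all 9). Sugar ABC transporters (-1.51), phosphotransferase uptake (-1.37), ribosomal proteins (-1.23, 31 of 57), pyruvate metabolism (-0.59) and metal transport (-0.25) followed. Fatty acid synthesis (2.67, 12 of 13), purine (1.21, 9 of 15 up and 1 down), pyrimidine (1.09, 7 of 11) and cold shock genes (0.75, 1 of 6) had the highest, followed by chaperones (0.40), the cell wall (0.34) and glycolysis (0.31). The F1F0-ATPase had a median of -0.12 and no gene past the limit. Glycolysis and metal transport lay within the random range with no read minimum or with random lists not matched on expression, and glycolysis also with random lists drawn without ribosomal proteins.

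Across genes the acid responses of the 2 strains had a Pearson correlation of -0.69 (95% interval over resampled genes -0.73 to -0.65) and a Spearman correlation of -0.53. Genes are not independent replicates, and the 2 responses share no library. Of genes past the rule in both, 80 went in opposite directions and 0 in the same one, where independent lists would give 6.26 and 4.47. Among the 2205 genes with enough reads in both strains' pairs, 182 passed in NZ9000, and 167 of these had the opposite sign in WH101. The 4 libraries were also split 2 against 2, which was not among the choices fixed before the data were examined. Genes whose nearest libraries lay at least 2-fold apart numbered 0 for WH101 against NZ9000 and 0 for pH 4 against pH 7. For the split that joins NZ9000 pH 4 with WH101 pH 7 they numbered 65. In 51 of these, thiamine phosphate synthase (LLNZ_RS06160) first, the joined libraries were the higher ones.

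**Figure D4:**
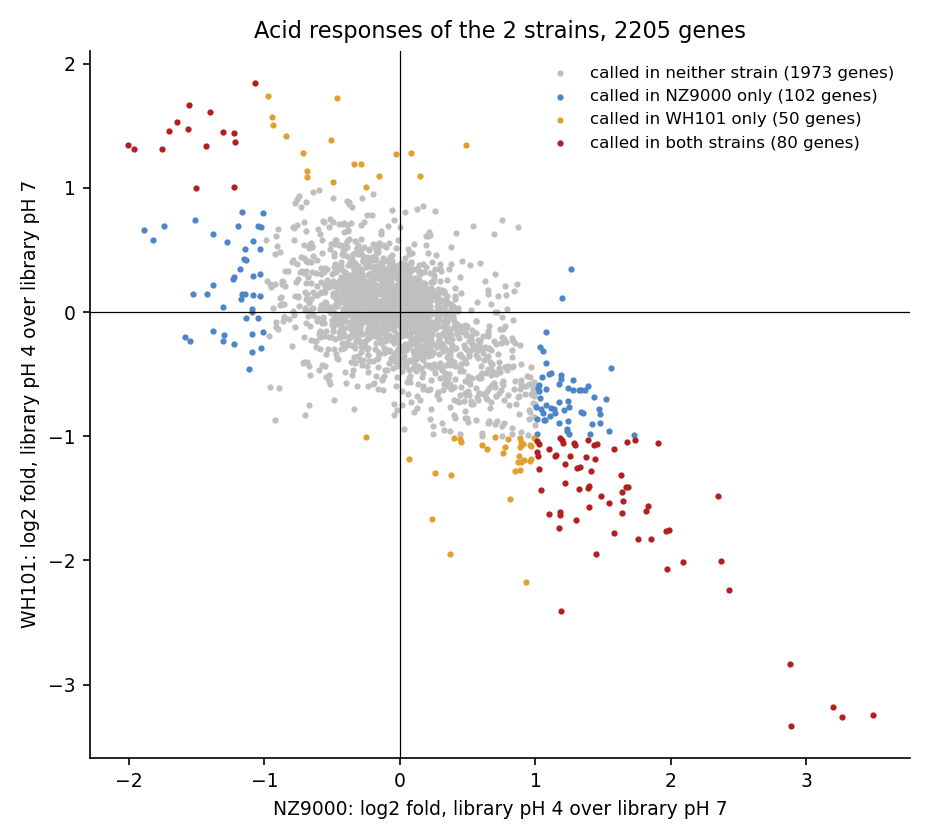
Each point is a gene, with its log2 fold (pH 4 over pH 7) in NZ9000 on the x axis and in WH101 on the y axis, 1 library per group. All 80 genes past the size rule in both strains lie in the upper left or lower right quadrant.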

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

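The tests of explanations in this part were chosen after the results were seen; the lists and the difference of responses were not. The genes and lists given first were picked out because the 2 strains, as labelled, moved in opposite directions under the same contrast of pH. The cold shock genes, given last, were low in a single library. With 1 library per group, the difference was not tested against any spread between cultures. Values are differences of log2 folds, WH101 minus NZ9000.

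In all, 80 genes passed the size rule in both strains in opposite directions, and 13 gene lists stood apart in opposite directions. The lists higher in NZ9000 and lower in WH101 were branched-chain amino acid biosynthesis (-3.08), glutamine and glutamate (-2.91), arginine deiminase (-2.50), peptide transport (-1.90), histidine biosynthesis (-1.82), sugar ABC transporters (-1.51), phosphotransferase uptake (-1.37), ribosomal proteins (-1.23) and pyruvate metabolism (-0.59). Those that went the other way were fatty acid biosynthesis (2.67), purine (1.21) and pyrimidine biosynthesis (1.09) and chaperones and proteases (0.40).

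Of the named genes 36 passed in both strains with opposite signs. For thiamine and nitrogen supply these were LLNZ_RS06160 (-6.73), LLNZ_RS06155 (-6.38), LLNZ_RS06150 (-6.22), P-II (LLNZ_RS04665, -5.71), the ammonia permease (LLNZ_RS04660, -4.67) and glutamate synthase genes LLNZ_RS06000 (-3.59) and LLNZ_RS05995 (-3.36). Amino acid synthesis gave LLNZ_RS06525 (-4.38), LLNZ_RS06520 (-3.39), threonine dehydratase LLNZ_RS06475 (-3.09), acetolactate synthase genes LLNZ_RS06485 (-2.80) and LLNZ_RS06490 (-2.69) and histidinol-phosphate aminotransferase LLNZ_RS06590 (-2.26). Arginine breakdown gave LLNZ_RS11560 (-3.73), LLNZ_RS11565 (-3.42) and ornithine carbamoyltransferase LLNZ_RS11575 (-2.50). Uptake genes were oppA (LLNZ_RS03630, -4.10), permease LLNZ_RS03625 (-4.04), sugar permeases LLNZ_RS03825 (-3.09) and LLNZ_RS03830 (-2.37) and zinc genes LLNZ_RS12015 (-2.95) and LLNZ_RS12010 (-2.52). Others in this direction were 4-alpha-glucanotransferase (LLNZ_RS09365, -3.83), 2-dehydro-3-deoxygluconokinase (LLNZ_RS04430, -3.60), an alcohol dehydrogenase (LLNZ_RS04835, -2.79) and a mobilization protein (LLNZ_RS06960, -2.77).

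Fatty acid genes went the other way: LLNZ_RS08945 (3.35), LLNZ_RS08915 (3.17), LLNZ_RS08935 (3.16), LLNZ_RS08920 (3.04) and fabF (LLNZ_RS08925, 3.02). So did the MarR family regulator (LLNZ_RS08950, 3.28), a ketoacyl-ACP reductase outside the list (LLNZ_RS08930, 3.22), bioY2 (LLNZ_RS01725, 3.07), lumazine synthase (LLNZ_RS07695, 2.92) and the transporter yjeM (LLNZ_RS09965, 2.77).

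The opposite responses are the pattern most in need of an explanation. Bias by gene length and expression level is argued against, since the correlation of the responses stayed at -0.69 after medians over bins of both were subtracted. The same library entered under 2 labels is argued against too: the closest pair had a chi-square per gene of 44.9, where 100 simulated pairs drawn from a single library gave at most 1.09. The simulated pairs hold counting error only, so they cannot address 1 culture prepared as 2 libraries. Correlations of log2 CPM were 0.997 and 0.995 in the cross pairs and 0.980 to 0.988 in the others. An exchange of labels between a pair of libraries stays open: 65 genes split the libraries by the cross pairing and 0 by strain or by pH. An exchange may give this. Opposite responses from a shared pH 7 level would not. They would also need strains that differ at pH 7 (93 genes past the rule). Each strain at pH 4 would further have to lie near the other at pH 7 (6 and 13 genes). The libraries as labelled show both. An exchange makes demands of its own. If it was between strains, acid would have moved only 6 and 13 genes past the rule within a strain. If it was within a strain, the strains would differ by only 6 and 13 such genes at the same pH. So the 2 explanations cannot be told apart. Genes silent in both libraries of a strain and read in both of the other numbered 0. Genes silent in both libraries of a cross pair and read in both of the other pair also numbered 0. Such genes could speak only to an exchange between strains, since an exchange within a strain leaves them in place. With 0 of either kind they decide nothing. Nor can these data say which pair of labels would be involved, and a difference in growth state between cultures was not tested.

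Cold shock genes were low in the library labelled NZ9000 pH 4 alone, with a median of -0.78 against NZ9000 pH 7. Library scaling shifts all genes of a library alike, so it can move this median but cannot set the list apart from random lists. The list lay at percentile 0.02 of those matched on expression, which argues against scaling as the whole cause. The median stayed between -0.88 and -0.73 under 5 scalings, but these lay close together and test only small shifts. Loss of short genes is argued against as well: 125 other genes of 150 to 250 nt had a median of 0.0104, and the cold shock list lay at percentile 0.13 of random lists drawn from them. A response of the parent to acid stays open as a hypothesis only if the label of that library holds, which an exchange of labels would undo. Culture-to-culture variation is untested, and these genes are uncertain since near-identical copies can share reads.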

How the results depend on the processing

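The counts on cross pairs and the correlation over genes past the rule in neither strain were chosen after seeing the data; the other alternatives were not. The size limit moved every count: with 4-fold, 10 genes passed in NZ9000, 12 in WH101, 7 between strains at pH 7, 18 at pH 4 and 122 for the difference of responses, and with 1.5-fold 473, 365, 288, 473 and 775, since the limit itself sets how many genes are counted. Under the other alternatives these 5 counts stayed within 1.5 times, and no gene was called in the opposite direction. Apart from the size limit, the share of higher genes moved with scaling: for NZ9000, 126 higher and 61 lower became 99 and 79 by total gene reads, 89 and 66 by RPKM, 94 and 77 by the authors' calls but 147 and 52 by the upper quartile; at pH 4, 52 and 147 became 68 and 119 by the authors' calls but 39 and 170 by the upper quartile. The 4-fold limit moved the split further, to 9 and 1 in NZ9000, 0 and 12 in WH101, 7 and 0 between strains at pH 7 and 1 and 17 at pH 4. Total gene reads also moved the median of all genes, from -0.03 to -0.13 in NZ9000 and from 0.04 to 0.12 between strains at pH 4; folds above are relative to TMM. The correlation of responses was -0.77 with a minimum of 500 reads (1739 genes) and -0.77 with 500 reads in every library (1500 genes), where counting error is smaller, and -0.47 over the 1973 genes past the rule in neither strain, which leaves out the largest folds by construction; the other alternatives gave -0.70 and -0.71.

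Membership by symbol alone left 15 lists with members, of which 1 stood apart in NZ9000, 2 in WH101, 2 between strains at pH 7, 1 at pH 4 and 1 for the difference, against 17, 15, 16, 17 and 17 of 31; the cause is that most genes have no symbol. No list that stood apart changed the sign of its median under another setting. The counts of 6 and 13 on cross pairs ran up to 61 and 110 with 1.5-fold and fell to 0 and 0 with 4-fold. They depend on the read minimum too, with 27 and 37 for none and 1 and 5 for 500. The count of 6 became 3 with a prior of 5 and 3 by RPKM. Low reads may play a part, but RPKM also differs in scaling, and the 2 were not separated. Of 534 named gene values, 172 past the rule, RPKM lost 10 and gained 1, and none of the largest folds was lost under the 6 alternatives run on named genes, which did not include the read minimum or the size limit. Leaving out rRNA and tRNA genes was not run, since the tables hold none. Genes near 50 reads have wide intervals, and with the 2-fold limit a smaller change was not called at any depth.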

Other observations

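The tests and groups in this part were chosen after seeing the data. Among GO process terms of 4 to 80 genes, 23 of 102 stood apart from matched random lists in NZ9000, and some are in no list described above. The percentile limits alone would give 5.1 if terms were made of independent genes. Terms can share genes and hold genes that move together, so 5.1 is not a firm expectation. The Leloir genes for galactose use had a median of 0.81 in NZ9000 (percentile 99.37) and -0.63 in WH101 (percentile 0.9); galactokinase (LLNZ_RS11195) read 0.73 and -0.65, and mutarotase (LLNZ_RS11200) 0.88 and -0.67, all under the 2-fold limit. Glycogen synthesis had a median of 0.92 in NZ9000 (percentile 99.82) with 2 of 4 genes up, the glucose-1-phosphate adenylyltransferase genes LLNZ_RS09355 and LLNZ_RS09360 (1.06 for the latter), and -0.37 in WH101 (percentile 5.61). Among 14 amino acid transport genes, an amino acid permease (LLNZ_RS00630) rose in NZ9000 (1.22) and fell in WH101 (-1.37), as did transporter LLNZ_RS11570 (1.67 and -1.41), while a lysine permease (LLNZ_RS12430) fell in NZ9000 (-1.01). Enzymes of folate synthesis had a median of 0.54 in WH101 against NZ9000 at pH 4 (percentile 99.595), with no gene past the limit.

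A stretch of locus tags from LLNZ_RS04110 to LLNZ_RS04360, holding 15 genes of the phage list, read highest by its median in the library labelled WH101 pH 4. It is 1 of 5 stretches built from that list. In WH101 pH 4 against pH 7 the other 4 had no gene past the limit and fewer measured genes. Their medians were -0.10 (13 genes), -0.35 (11 genes) and -0.01 (11 genes), and the last had only 1 measured gene, at -0.50. Genes of the LLNZ_RS04110 stretch had a median of 0.58 against WH101 pH 7 (35 of 44 above 0, 9 higher and 1 lower). Against NZ9000 pH 4 it was 0.25 (28 of 43 above 0, 5 higher and 1 lower). Against NZ9000 pH 7 it was 0.45 (39 of 43 above 0, 2 higher and 0 lower). The terminase (LLNZ_RS04255) had 158 reads in NZ9000 pH 7, 270 in NZ9000 pH 4, 218 in WH101 pH 7 and 349 in WH101 pH 4. The scaffold protein (LLNZ_RS04290) had 469, 346, 300 and 683.

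Between the library labelled WH101 pH 4 and that labelled NZ9000 pH 7, the genes past the rule were the terminase (LLNZ_RS04255, 1.17), hypothetical proteins LLNZ_RS04355 (1.20) and LLNZ_RS02575 (1.01), comFC (LLNZ_RS07485, -1.03), a transcriptional regulator (LLNZ_RS06225, -1.11) and a sigma70 factor (LLNZ_RS12265, -1.38). Between the library labelled WH101 pH 7 and that labelled NZ9000 pH 4, the bacteriocin gene LLNZ_RS06350 (1.55), a transcriptional regulator (LLNZ_RS00640, 1.19) and cold shock genes LLNZ_RS06355 (1.07) and LLNZ_RS09230 (1.07) were among the 11 higher genes, and 3-isopropylmalate dehydrogenase (LLNZ_RS06520, -1.09) was 1 of the 2 lower ones.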
